A study of Homo sapiens with 6 samples.

How the data were processed

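Total RNA of 6 samples of U87MG cells was labelled and hybridised to human transcriptome arrays, per the labels' protocols and the series' design text. The labels name the hairpin of each sample (shGFP, sh50 or sh52) and its replicate number, 1 or 2. The series' design text names 2 lentiviral hairpin clones whose last digits match the names sh50 and sh52; it states no target for either. The labels do not say whether replicates came from separate infections or cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

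The deposited values were made by the authors with RMA in Expression Console at the core level, per the labels. These deposited values are read here as log2 expression values. Transcriptome Analysis Console is named in the submitters' processing notes. Its version, the background settings and the probe annotation are not given in the sources used here, nor is the base of the logarithm. The base is taken as 2, as is usual for RMA. The values, between 1.38 and 19.9, do not settle the base or whether the signal was scaled further. The direction of a difference does not depend on the base. A fold depends on the base and on any such scaling, so folds below hold only for base 2 without it.

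The table held 70523 features, of which 67528 were transcript clusters. The other 2995, whose identifiers are of other kinds (probe sets of exons, junctions and controls among them), were left out, except 8 bacterial and phage spike-in controls used as a check. Transcript clusters were kept where their mean over the 6 arrays was at or above the median of 3.98, which left 33764. Platform annotation listed 25324 of the 67528 transcript clusters, 23781 with 1 gene symbol and 1543 with several, and the other 42204 were unnamed here. Symbols were updated through a gene table of the assembly GRCh38.p14, by gene identifier for 21497, by symbol for 1974 and by older symbol for 306, and 4 were kept as given. Coordinates are not given because the build behind the array's annotation is not named in the sources used here. A gene was represented by its brightest transcript cluster with that symbol alone, which gave 14376 genes.

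Group means were fitted with limma 3.58.1 in R 4.3.3 over all 6 arrays, which share one estimate of the spread with 3 residual degrees of freedom. Contrasts were tested with moderated variances (2.67 prior degrees of freedom) and Benjamini-Hochberg adjustment, two-sided, at an adjusted p of 0.05. Gene lists were fixed before the data were examined, 18 lists with 671 memberships, and tested with camera at a preset correlation of 0.01, adjusted over the 18 lists. Members without a transcript cluster of their own symbol above the filter were not tested. An estimated correlation and fry, a rotation test of each list by itself, were run as alternatives. With an estimated correlation 0 lists passed in any comparison, and 0 passed with fry, while 5 lists passed camera with sh50, 10 with sh52, 10 with the mean of both and 6 between the hairpins. In simulated data without any change, where members of the mitosis list shared a correlation of 0.8 as estimated here, camera with its preset correlation gave a p under 0.05 in 71% of 200 draws. In 2.5% of those draws the p was as small as the one observed.

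The rule for named genes, also fixed beforehand, took SAT1, the 12 largest changes each way among called genes of the mean of both hairpins against shGFP, and 5 each way in the other comparisons, where the arrays of the groups did not overlap. Where none passed, as here, it took the 5 protein-coding genes with the smallest p each way, and from each list the 4 members with the largest change, or 2 where the list did not pass. The fit was tested on simulated data in which 200 transcripts were changed, over 5 draws, and called 20 of 167820 unchanged transcripts. A change shared by both hairpins was set against 100 simulations of unchanged groups with shared controls.

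Alternatives fixed beforehand were the replicate number as a block, no filter on dim features, a filter at the 75th percentile, single-symbol features only, trend and robust options, another quantile normalization, centring of the arrays, only the groups compared, each array left out in turn, a 1.5-fold threshold, and for the lists an estimated correlation, fry and the mean of all features of a gene. Added after the data were seen were a threshold of unadjusted p 0.05 with 2-fold, a fit without moderation, and the spike-in mean as a covariate. In the single-hairpin comparisons and between the hairpins, alternatives are given for the lists that passed camera there. Splits of the 6 arrays into 2 and 4 number 15.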

Results

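Gene expression was measured in U87MG cells, a human glioblastoma line, after infection with lentiviruses carrying short hairpin RNAs. The cells carried a hairpin against GFP (shGFP, the control) or 1 of 2 hairpins named sh50 and sh52. SAT1, the gene named in the series title, encodes the acetyltransferase that limits the rate of polyamine breakdown. Each group had 2 arrays, 6 in all, of cells grown for 5 days after drug selection. The median over all array features lay between 3.98 and 4.12 (log2) on the 6 arrays. The comparisons ask which transcripts differ between each hairpin and the control, between the mean of both hairpins and the control, and between the hairpins.

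SAT1 was read on each array first. It stood at 9.45 and 8.96 (log2) on the shGFP arrays and at 9.36 and 8.35 on the sh50 arrays. On the arrays labelled sh52 it stood at 10.83 for replicate 1 and 7.84 for replicate 2. The array labelled sh52 replicate 1 thus carried more SAT1 than any other array, and sh50 replicate 1 lay between the controls. A hairpin against SAT1 would lower it, but the design text states no target for sh52. Only 2 of the 4 hairpin arrays lay below both shGFP arrays. The group means were 9.20 ± 0.34 (SD, n = 2) for shGFP, 8.85 ± 0.72 for sh50 and 9.34 ± 2.11 for sh52. By limma the change was -0.35 ± 0.96 (SE) for sh50 (adjusted p = 0.982), 0.13 ± 0.96 for sh52 (adjusted p = 0.98) and -0.11 ± 0.83 for the mean of both hairpins (adjusted p = 0.986). None passed the threshold, and the 95% interval of the last ran from -2.17 to 1.95. Without the array labelled sh52 replicate 1, the change was -1.36 for sh52 and -0.86 for the mean of both. With the mean of the spike-in controls as a covariate, a fit chosen after the data were seen, it was -1.15 ± 0.56 (SE) for sh50, -1.78 ± 0.72 for sh52 and -1.47 ± 0.57 for the mean of both (adjusted p = 0.565, 0.849 and 0.616). The sh50 arrays had nearly equal spike-in means (9.26 on both), so the slope of that covariate came from the shGFP and sh52 pairs. In both pairs replicate 1 had the higher spike-in mean, so the covariate also followed the replicate number. The array labelled sh52 replicate 1 had the highest spike-in mean (9.83), so these values lean on the array in doubt. They do not show a fall of SAT1. Against the shGFP array of the same replicate number, SAT1 differed by -0.085 for sh50 and by 1.39 for the array labelled sh52 replicate 1. For number 2 the differences were -0.62 and -1.12. Every direction given below for sh52, or for the mean of both hairpins, draws on the array labelled sh52 replicate 1.

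**Figure D1:**
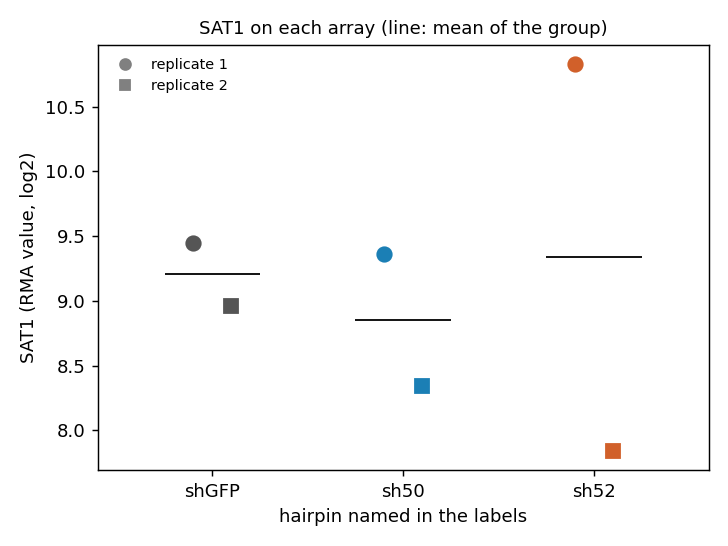
SAT1 (RMA value, log2, vertical axis) on each of the 6 arrays by the hairpin named in the labels (horizontal axis); circles are replicate 1, squares replicate 2 and lines the group means. The array labelled sh52 replicate 1 lay highest at 10.83 and sh52 replicate 2 lowest at 7.84.

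Genes of cell division were lower on the hairpin arrays than on the controls. In the mean of both hairpins against shGFP, all 58 measured genes of mitosis and G2/M had a lower point estimate, with a median log2 change of -1.51. For 57 of them all 4 hairpin arrays lay below both controls. PLK1, a kinase of mitotic entry, was 3.95-fold lower (log2 change -1.98 ± 0.41, SE), and the kinetochore genes CENPF and CENPE differed by -1.90 ± 0.39 and -1.83 ± 0.42. SGO1, which protects centromeric cohesion, differed by -1.82 ± 0.41. MELK, a mitotic kinase taken for its known link to SAT1, differed by -1.59 ± 0.43. Called members of the mitosis list numbered 0 over all transcripts and 55 adjusted over the list alone. The list as a whole passed camera with its preset correlation (adjusted p = 1.72e-36), but not with a correlation estimated from these arrays (adjusted p = 0.651 with an estimated correlation). MELK and EZH2 were known beforehand as genes linked to SAT1, so the mitosis and polycomb lists were not chosen blind.

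DNA replication and repair genes lay on the same side. Of 50 replication and G1/S genes, 49 had a lower estimate, and for 42 all 4 hairpin arrays lay below both controls, with a median of -1.01 (camera, adjusted p = 6.65e-20; adjusted p = 0.663 with an estimated correlation). DBF4, which activates the kinase that fires replication origins, differed by -1.61 ± 0.32 (SE), and RFC3, a clamp loader subunit, by -1.60 ± 0.52. Without sh50 replicate 2 the replication median was -0.66, still called. POLA1 and MCM3, parts of the replication machinery, differed by -1.49 ± 0.39 and -1.41 ± 0.45. Of 39 genes of homologous recombination and DNA repair, 35 had a lower estimate, and for 24 all 4 hairpin arrays lay below both controls, with a median of -0.61 (camera, adjusted p = 2.69e-10; adjusted p = 0.663 with an estimated correlation). POLQ was 2.96-fold lower, CLSPN 2.83-fold, FANCI 2.70-fold and FANCB 2.61-fold. No member of either list was called over all transcripts, and 0 were called adjusted over the list alone.

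Extracellular matrix genes and genes of the response to low oxygen were higher in the mean of both hairpins. Of 42 matrix and mesenchymal genes, 37 had a higher estimate, and for 15 all 4 hairpin arrays lay above both controls, with a median of 0.56 (camera, adjusted p = 2.72e-08; adjusted p = 0.651 with an estimated correlation). CHI3L1, a secreted glycoprotein used as a mesenchymal marker, was 8.27-fold higher (log2 change 3.05 ± 0.54, SE), and the laminin gene LAMA4 was 4.64-fold higher (2.21 ± 0.32). MMP3, which encodes a matrix protease, differed by 2.53 ± 1.13 and the protease inhibitor gene TIMP3 by 1.85 ± 0.78. Of this list 3 members were called adjusted over the list alone. Of 34 hypoxia and glycolysis genes, 31 had a higher estimate, and for 14 all 4 hairpin arrays lay above both controls, with a median of 0.53 (camera, adjusted p = 1.22e-06; adjusted p = 0.684 with an estimated correlation). ANGPTL4, ALDOC, P4HA1 and NDRG1 differed by 2.80 ± 0.51, 1.63 ± 0.71, 1.31 ± 0.64 and 1.27 ± 0.51, and 0 members were called adjusted over the list alone. Without the array labelled sh52 replicate 1, ALDOC stood at 0.99, P4HA1 at 0.72, NDRG1 at 0.82 and TIMP3 at 1.11, and without shGFP replicate 1 MMP3 stood at 1.31. The matrix median was 0.19 on sh50 replicate 2, 0.53 to 1.13 on the other hairpin arrays and 0.18 on shGFP replicate 1. The list's change was 0.30 without shGFP replicate 2 and 0.32 without sh50 replicate 1, still called. The hypoxia median was 1.37 on the array labelled sh52 replicate 1 and 0.16 to 0.39 on the other hairpin arrays. Without that array the list's change was 0.27. With the mean of the spike-in controls, which also stood highest on that array, as a covariate it was 0.20, and the call was lost (adjusted p = 0.427).

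**Figure D2:**
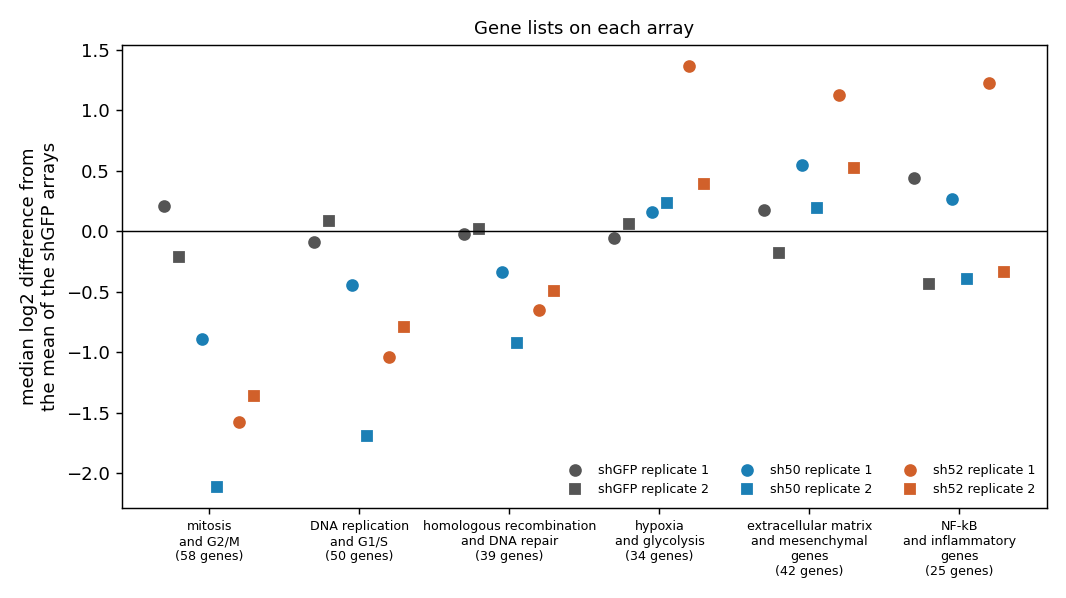
Median log2 difference of each gene list from the mean of the shGFP arrays (vertical axis) on each of the 6 arrays, with colours for the hairpin and circles and squares for replicates 1 and 2. The mitosis median lay between -2.11 and -0.89 on the 4 hairpin arrays, and the array labelled sh52 replicate 1 lay highest for hypoxia, at 1.37, and for inflammatory genes, at 1.23.

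Smaller differences were found in 5 other lists. Interferon response genes had a median of 0.20 (26 of 33 with a higher estimate; camera, adjusted p = 0.00972; adjusted p = 0.755 with an estimated correlation). Of these IFI6 differed by 1.29 ± 0.43 (SE), SAMD9L by 1.20 ± 0.27, IFITM3 by 1.20 ± 0.24 and PARP14 by 0.71 ± 0.49. Neuronal markers had a median of 0.22 over the 8 genes tested of 20 in the list (camera, adjusted p = 0.0263, and 0.651 with an estimated correlation). SNAP25, of synaptic vesicle release, and MAP2, of the cytoskeleton, were 2.83-fold and 2.34-fold higher, and 2 members of this list were called adjusted over the list alone. ENO2, also a member of the hypoxia list, and GAD1 differed by 0.36 ± 0.57 and 0.27 ± 0.15. Oxidative phosphorylation genes had a median of 0.084 (camera, adjusted p = 0.0203; adjusted p = 0.755 with an estimated correlation), with COX7B at 0.56, COX5B at 0.52, NDUFB5 at 0.46 and NDUFA2 at 0.45. Cytosolic ribosomal protein genes had a median of -0.13 (camera, adjusted p = 0.00972; adjusted p = 0.757 with an estimated correlation), with RPL14 at -0.41, RPL12 at -0.40, RPL7 at -0.37 and RPS28 at 0.38. The polycomb and DNA methylation machinery had a median of -0.046 (camera, adjusted p = 0.0453; adjusted p = 0.684 with an estimated correlation). Of its 28 genes 15 had a lower and 13 a higher estimate. In that list EZH2, the methyltransferase of polycomb complexes, differed by -1.31 ± 0.33, DNMT1 by -0.99 ± 0.32, RBBP4 by -0.99 ± 0.21 and PHF19 by -0.77 ± 0.27. In these lists other than neurons 0 members were called adjusted over the list alone. Each of the 5 calls was lost without some single array. Interferon genes stood at 0.069 without shGFP replicate 1 and 0.13 without sh52 replicate 2, and oxidative phosphorylation at -0.011 and 0.050. Ribosomal protein genes stood at -0.048 without shGFP replicate 2 and -0.074 without the array labelled sh52 replicate 1, and neuronal markers at 0.16 and 0.055. The polycomb call was lost without any 1 of shGFP replicate 2 (-0.044), sh50 replicate 1 (-0.025), the array labelled sh52 replicate 1 (-0.023) or sh52 replicate 2 (-0.049). Without shGFP replicate 1, and still called, polycomb stood at -0.17, ribosomal protein genes at -0.27 and neuronal markers at 0.37. Without shGFP replicate 2 interferon genes stood at 0.32 and oxidative phosphorylation at 0.22, without sh50 replicate 2 interferon genes at 0.078 and without the array labelled sh52 replicate 1 oxidative phosphorylation at 0.16, all still called. The polycomb call was also lost with the replicate number as a block (adjusted p = 0.0993), with trend and robust options (0.0655) and with the spike-in covariate (-0.0077), and the ribosomal and neuronal calls with a filter at the 75th percentile (adjusted p = 0.0604 for both) and with the spike-in covariate (0.0090 and 0.013). Without shGFP replicate 1, IFI6 stood at 0.79, SAMD9L at 0.76, PARP14 at 0.14, SNAP25 at 0.99, COX5B at 0.30, GAD1 at 0.17 and RPS28 at -0.32. Without shGFP replicate 2, PARP14 stood at 1.28, RPL12 at -0.26 and RPS28 at 1.09, and without the array labelled sh52 replicate 1, RPL14 at -0.27 and ENO2 at -0.13. Without sh50 replicate 2 PARP14 stood at 0.36.

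The other 8 lists did not pass camera. Polyamine metabolism had a median of -0.078 over 22 genes (adjusted p = 0.827), with ODC1, the first enzyme of polyamine synthesis, at -1.77 ± 0.91 (SE) and SLC3A2 at -0.74 ± 0.54. The p53 targets had a median of -0.0033 and a mean of 0.047, of opposite sign (adjusted p = 0.827), with TP53INP1 at 1.20 and RRM2B at 0.78. The unfolded protein and integrated stress response had a median of -0.060 (adjusted p = 0.827), with DDIT4 at 1.55 and SLC7A5 at -1.12. Cholesterol synthesis stood at 0.18 (adjusted p = 0.142), with HMGCS1 at 1.11 and MSMO1 at 0.85. Inflammatory NF-kB genes stood at 0.076 (adjusted p = 0.251), with CCL2 at 1.79 and LIF at -1.54. Glial and neural stem genes stood at 0.020 (adjusted p = 0.626), with SLC1A3 at 0.78 and PDGFRA at 0.71. Markers of blood and immune cells stood at 0.069 (adjusted p = 0.61), with LCP1 at 0.51 and ITGAX at 0.19. Markers of epithelial cells stood at 0.090 (adjusted p = 0.325), with KRT8 at 0.30 and MUC1 at 0.29. In these 8 lists 0 members were called adjusted over the list alone. The direction of several depended on which control was left out. Without shGFP replicate 1 the p53 targets stood at -0.28 and the inflammatory genes at 0.88. Without shGFP replicate 2 they stood at 0.32 and -0.23. Each such fit sets a control of 1 number against hairpin arrays of both, so the turns cannot be told from replicate number. Against the shGFP array of the same number, p53 targets differed by 0.26 (sh50) and 0.056 (sh52) in number 1, and by -0.14 and 0.016 in number 2. Inflammatory genes differed by -0.052 and 0.35, and by 0.11 and 0.16. Without the array labelled sh52 replicate 1 the inflammatory genes stood at -0.20. Camera called the p53 targets without either control, in opposite directions (adjusted p = 0.046 and 0.0101). It called the inflammatory genes without shGFP replicate 1 (adjusted p = 0.000191), sh50 replicate 2 (0.41, adjusted p = 0.0334) or sh52 replicate 2 (0.40, adjusted p = 0.000368). It also called cholesterol synthesis without sh50 replicate 1 (0.25, adjusted p = 0.0149) and glial genes without shGFP replicate 1 (0.059, adjusted p = 0.046). With the spike-in covariate it called the p53 targets upward (0.39, adjusted p = 9.69e-05) and the inflammatory genes downward (-0.79, adjusted p = 7.83e-06). Both calls used the preset correlation, while the estimated one was 0.52 for p53 targets and 0.53 for inflammatory genes. In the shGFP and sh52 pairs, which set the covariate's slope, the number 1 array had the higher spike-in mean (9.25 against 8.88, and 9.83 against 9.24). The covariate thus cannot be told apart from the replicate number. In sh50, with nearly equal spike-in means, numbers 1 and 2 differed by 0.60 for inflammatory genes and -0.056 for p53 targets. With an estimated correlation neither list passed in the main fit (camera, adjusted p = 0.937 and 0.905). The genes named for these 8 lists, other than CCL2, each moved by over 1.5 times or turned without some single array. Without shGFP replicate 1 and replicate 2 in turn, TP53INP1 stood at 0.053 and 2.34, RRM2B at -0.0060 and 1.57, LIF at 1.20 and -4.27, SLC3A2 at -1.56 and 0.075, and ITGAX at 0.34 and 0.030. Without shGFP replicate 2 SLC7A5 stood at -0.64. Without sh50 replicate 2, ODC1 stood at -1.02, TP53INP1 at 0.67, LIF at 0.12, HMGCS1 at 0.73, MSMO1 at 0.49, SLC1A3 at 0.36 and KRT8 at 0.17, and without sh50 replicate 1 LCP1 stood at 0.27. Without the array labelled sh52 replicate 1, DDIT4 stood at 0.92, HMGCS1 at 0.70, MSMO1 at 0.44, PDGFRA at 0.46 and MUC1 at 0.18.

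Of single genes, the complement gene C3 had the smallest p in the mean of both hairpins. It stood at 8.69 ± 0.28 (SD, n = 2) on the shGFP arrays, 12.87 ± 0.74 with sh50 and 12.06 ± 0.61 with sh52, which is 13.7-fold higher (log2 change 3.78, 95% interval 2.82 to 4.73). TNFRSF11B, a decoy receptor of bone remodelling, was 4.59-fold higher, TNFRSF21 2.92-fold, PCDHGC5 2.66-fold and RECK, an inhibitor of matrix proteases, 2.24-fold. POMK was 3.37-fold lower, SYNE2 2.76-fold, LIN7C 2.59-fold, SERTAD2 2.51-fold and SGPL1, the lyase that degrades sphingosine phosphate, 2.32-fold. None passed the correction (limma, adjusted p = 0.456 for each), though all 4 hairpin arrays lay on the same side of both controls for each of them except SGPL1, where 3 did. By limma 0 of 33764 transcripts passed, while 3102 (9.19%) had an unadjusted p under 0.05 against 1688.2 by chance, 1470 higher and 1632 lower. Without shGFP replicate 1 that count was 1718 (5.09%), about the chance number, and without shGFP replicate 2 it was 2039 (6.04%). A group left with 1 array has a less precise mean, here and in the comparisons below. A lower count there does not show that the excess rests on the array left out. A fit without moderated variances also called 0 in each of the 4 comparisons. On simulated data the same fit called 14.6% of transcripts changed by a log2 of 1, 57.9% at 2 and 77.6% at 3. Transcripts were drawn independently there, and each residual variance, from 3 residual degrees of freedom, was taken as the true one. The shares are therefore not detection rates for these arrays, where C3 at 3.78 was not called.

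With sh50 against shGFP, the genes of cell division again lay lower. All 58 mitosis genes and all 50 replication genes had a lower estimate, with medians of -1.52 and -1.10 (camera, adjusted p = 3.33e-34 and 4.81e-20; adjusted p = 0.824 for both with an estimated correlation). Repair genes stood at -0.60 (adjusted p = 3.18e-09; adjusted p = 0.824 with an estimated correlation). Much of this lay on 1 array: without sh50 replicate 2 the mitosis, replication and repair medians were -0.89, -0.45 and -0.34, and without sh50 replicate 1 they were -2.11, -1.69 and -0.92, still called. Matrix genes stood at 0.35 (adjusted p = 0.000551; adjusted p = 0.853 with an estimated correlation) and ribosomal protein genes at -0.18 (adjusted p = 0.000551; adjusted p = 0.987 with an estimated correlation). The matrix call was lost without shGFP replicate 2 (0.18) or sh50 replicate 1 (0.20), and the ribosomal call without shGFP replicate 2 (-0.066). Matrix genes stood at 0.55 without sh50 replicate 2 and ribosomal protein genes at -0.29 without shGFP replicate 1, both still called. Both were lost with the spike-in covariate (0.17 and -0.078, adjusted p = 0.0803 for both). TNFRSF11B was 8.82-fold higher (log2 change 3.14 ± 0.27, SE), C3 18.1-fold, TNFRSF21 4.08-fold, PAMR1 3.46-fold and PCDHGC5 2.80-fold. CERS6, a ceramide synthase, was 3.99-fold lower, LIN7C 3.59-fold, DENND6A 3.31-fold, SERTAD2 3.03-fold and the linker histone gene H1-4 2.61-fold. None of these genes passed (limma, adjusted p = 0.475 for each), and 0 transcripts did, with 2784 (8.25%) at an unadjusted p under 0.05. Without sh50 replicate 2 these numbered 1508 (4.47%) and without shGFP replicate 1 they numbered 1605 (4.75%), both below the chance number. Adjusted over the list alone, 52 mitosis genes, 2 replication genes, 1 polycomb gene and 1 neuronal marker were called.

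With sh52 against shGFP, the mitosis, replication and repair lists stood at -1.53, -0.95 and -0.54 (camera, adjusted p = 1.65e-30, 2.35e-14 and 1.7e-08; adjusted p = 0.519 for each with an estimated correlation). Hypoxia genes stood at 0.79, with all 34 higher by estimate, and matrix genes at 0.74 (camera, adjusted p = 1.22e-11 and 1.23e-10; adjusted p = 0.519 for both with an estimated correlation). Interferon, cholesterol and neuronal genes stood at 0.23, 0.27 and 0.23 (adjusted p = 0.000376, 0.0093 and 0.0166; adjusted p = 0.519 for each with an estimated correlation). Oxidative phosphorylation genes stood at 0.13 (adjusted p = 0.0166; adjusted p = 0.619 with an estimated correlation). Inflammatory genes stood at 0.22 (adjusted p = 0.0426; adjusted p = 0.754 with an estimated correlation), and at -0.34 without the array labelled sh52 replicate 1 and -0.18 without shGFP replicate 2. Without the former the neuronal call was lost (0.078) and hypoxia stood at 0.39, still called. The cholesterol and neuronal calls were lost without shGFP replicate 2 (0.28 and 0.30), and the oxidative phosphorylation call without shGFP replicate 1 (-0.0043) or sh52 replicate 2 (0.033). The inflammatory call was lost without the filter on dim features (camera, 0.20, adjusted p = 0.0659) and with a filter at the 75th percentile (0.068, adjusted p = 0.13). With the spike-in covariate the list was called downward (camera, -0.80, adjusted p = 3.02e-06). That covariate followed the replicate number in the shGFP and sh52 pairs. Without sh52 replicate 2, hypoxia stood at 1.37, matrix genes at 1.13, inflammatory genes at 1.23, neuronal markers at 0.43 and interferon genes at 0.12. Without shGFP replicate 1 inflammatory genes stood at 1.33, neuronal markers at 0.44 and interferon genes at 0.092. Oxidative phosphorylation stood at 0.25 without shGFP replicate 2 and 0.24 without the array labelled sh52 replicate 1. These calls held. The spike-in covariate also ended the cholesterol and neuronal calls (0.18 and 0.050). SGPL1 was 5.12-fold lower (log2 change -2.36 ± 0.19, SE), POMK 5.97-fold, NGRN 4.36-fold, TMEM30A 3.74-fold and COLGALT1 2.40-fold. C3 was 10.4-fold higher, PCDHGC5 2.52-fold, KIRREL1 2.21-fold, RECK 2.15-fold and PLPPR4 2.11-fold. None of these genes passed (limma, adjusted p = 0.501 for each), and 0 transcripts did, with 2964 (8.78%) at an unadjusted p under 0.05. These numbered 1660 (4.92%) without the array labelled sh52 replicate 1, 5315 (15.7%) without sh52 replicate 2, 1844 (5.46%) without shGFP replicate 1 and 1902 (5.63%) without shGFP replicate 2. Adjusted over the list alone, 52 mitosis, 5 matrix, 1 hypoxia and 1 neuronal gene were called.

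The changes with the hairpins correlated across transcripts, as those of unchanged groups with shared controls also do. Their Pearson correlation was 0.596, against 0.498 in simulated unchanged groups with shared controls, and their covariance was 0.1 against 0.06, a difference of 0.04. By limma 0 transcripts passed with both hairpins. At an unadjusted p under 0.05, 462 were higher with both (277 in the simulation, 58.5 for independent lists) and 572 were lower (275 and 63.8). Much of the excess over independent lists came with the shared controls alone, since the simulation without change gave 277 and 275. A split of the 2 control arrays would leave 1 for each hairpin. Transcripts are not independent replicates. Genes that move together (estimated correlation 0.8 in the mitosis list) widen the range that unchanged groups can give. The excess over the simulation is therefore not shown to come from the hairpins.

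Between the hairpins, hypoxia genes were higher with sh52 than with sh50 by a median of 0.77, with 31 of 34 higher by estimate (camera on the difference, adjusted p = 7.19e-10; adjusted p = 0.996 with an estimated correlation). Without the array labelled sh52 replicate 1 hypoxia stood at 0.17, still called. The other 5 lists that passed, of matrix, inflammatory, cholesterol, interferon and ribosomal protein genes, each lost the call without 1 or more single arrays, and with an estimated correlation (adjusted p = 0.996 for each with an estimated correlation). Without the filter on dim features the last 4 lost it too (inflammatory 0.39, adjusted p = 0.171; cholesterol 0.28, adjusted p = 0.0644; interferon 0.12 and ribosomal 0.0996, adjusted p = 0.0936 for both). With the spike-in covariate the matrix call was lost (0.13) and the inflammatory genes stood at -0.33, not called. Cell division genes did not pass, with a mitosis median of -0.048 and mean of -0.013, while camera's direction was upward (adjusted p = 0.984). SGPL1 was 4.87-fold lower with sh52 (log2 difference -2.28 ± 0.19, SE), TMEM30A 4.97-fold, COLGALT1 3.57-fold, CMTM4 3.07-fold and RELCH 2.80-fold. TMEM65 was 4.81-fold higher, ADPGK, a glucokinase, 4.57-fold, the protease gene ADAM10 2.94-fold, CLPX 2.83-fold and DBT 2.24-fold. None passed (limma, adjusted p = 0.493 for each), and 0 transcripts did, with 2138 (6.33%) at an unadjusted p under 0.05. These numbered 1367 (4.05%) without the array labelled sh52 replicate 1 and 4483 (13.3%) without sh52 replicate 2. Adjusted over the list alone, 0 members of any list were called.

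The arrays also parted by replicate number. CXCL8, a neutrophil chemokine, stood at 15.99, 15.60 and 15.72 on the replicate 1 arrays of shGFP, sh50 and sh52, and at 9.96, 10.25 and 10.15 on the replicate 2 arrays. IL6 stood at 10.15, 10.10 and 11.57 against 5.75, 6.50 and 7.39. PTGS2, an enzyme of prostaglandin synthesis, stood at 13.42, 14.43 and 15.47 against 7.35, 8.39 and 8.14. These genes were chosen after their values were seen. Within replicate number 1 the mitosis median differed from shGFP by -1.12 for sh50 and -1.91 for sh52, and within number 2 by -1.88 and -1.19. The replication median differed by -0.39 and -0.97 within number 1 and by -1.80 and -0.86 within number 2, and the repair median by -0.24 and -0.67, and by -0.91 and -0.57. The hypoxia median differed by 0.23 and 1.34 within number 1 and by 0.16 and 0.22 within number 2. The matrix median differed by 0.40 and 0.88, and by 0.25 and 0.75. Each of these is a difference between single arrays and carries no test.

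**Figure D3:**
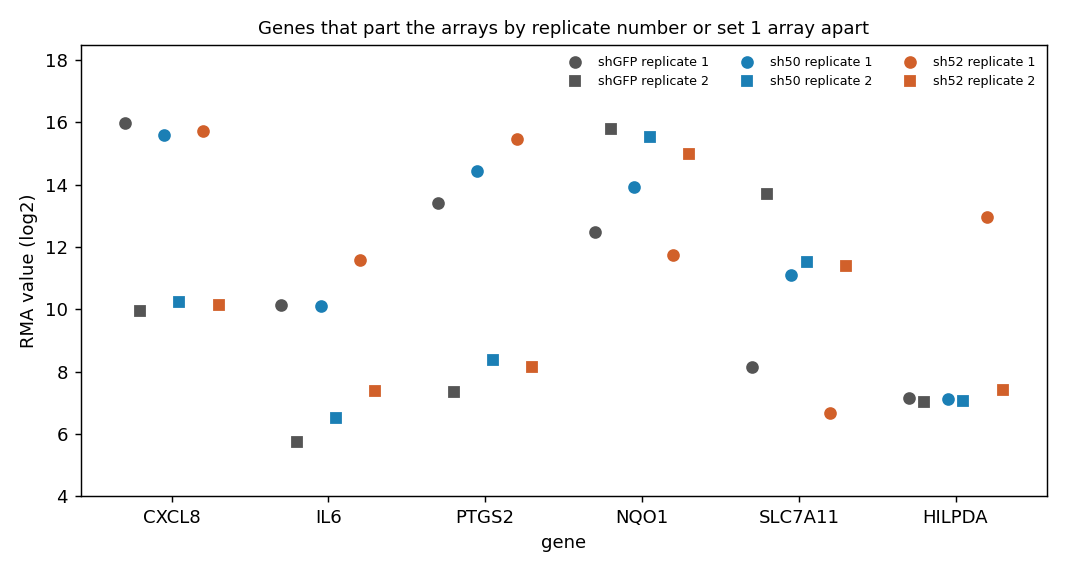
RMA values (log2, vertical axis) of 6 genes on each array, with colours for the hairpin and circles and squares for replicates 1 and 2. CXCL8, IL6 and PTGS2 lay higher on every replicate 1 array than on any replicate 2 array, and HILPDA stood at 12.98 on the array labelled sh52 replicate 1 against 7.04 to 7.42 elsewhere.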

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

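The tests of the array labelled sh52 replicate 1 alone, of SAT1, of exchanged or wrong labels and of MTAP were chosen only after the results were seen, as was the spike-in covariate. No group had enough arrays for a test of single outlying samples.

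Gene lists that differed between the hairpins were tested on the difference itself. With sh52 minus sh50, the median was 0.77 for hypoxia and glycolysis, 0.37 for matrix and mesenchymal genes, 0.40 for inflammatory genes, 0.28 for cholesterol synthesis, 0.18 for interferon response and 0.10 (0.0996) for ribosomal proteins. Camera's adjusted p was 7.19e-10, 0.000198, 0.0409, 0.0071, 0.0071 and 0.0143, and with an estimated correlation 0.996 for each. Without the array labelled sh52 replicate 1 the matrix, cholesterol and inflammatory calls were lost (0.087, 0.24 and -0.54), and without sh52 replicate 2 the interferon and ribosomal calls (0.10 and -0.065). Without sh50 replicate 1 the interferon and cholesterol calls were lost (-0.024 and 0.12), and without sh50 replicate 2 the matrix, inflammatory and ribosomal calls (0.19, 0.053 and 0.076). Without the filter on dim features the inflammatory, cholesterol, interferon and ribosomal calls were lost (adjusted p = 0.171, 0.0644, 0.0936 and 0.0936), and with the spike-in covariate the matrix and inflammatory calls (0.13 and -0.33). Other arrays left out gave larger differences. Interferon genes stood at 0.37 without sh50 replicate 2, and matrix genes at 0.615 without sh52 replicate 2. Inflammatory genes stood at 0.97 without sh50 replicate 1 and at 1.63 without sh52 replicate 2. Ribosomal protein genes stood at 0.26 without the array labelled sh52 replicate 1. A signal was also seen in data outside the comparisons. The 8 spike-in controls, of bacterial and phage sequence, were all highest on the array labelled sh52 replicate 1, by a mean of 0.65 (log2; 0.41 to 0.92) over the other 5 arrays.

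Genes of mitosis were lower on the 4 hairpin arrays, by a median of -1.51. The array labelled sh52 replicate 1 as the whole cause is argued against, since the median was -1.44 without it. Weaker target read from the spike-ins was not decided, though the median was -1.52 with their mean as a covariate. The sh50 arrays had nearly equal spike-in means (9.26 on both). Between numbers 1 and 2 the mitosis list differed by 0.42 in shGFP and -0.29 in sh52. These pairs pull the slope opposite ways, so the covariate could hardly move the median. A trend with expression level is also argued against, as 0% of 10000 lists matched on expression had a median as low (lowest -0.31). No relation with SAT1 mRNA level was shown across the arrays. Pearson r was 0.11 over 6 arrays (permutation p = 0.829) and Spearman rho 0.26 (permutation p = 0.658). Without the 2 arrays farthest from the SAT1 median (both labelled sh52), r was 0.81, which compares only sh50 with shGFP. On sh50 replicate 1 SAT1 (9.36) lay between the controls (9.45 and 8.96), and the mitosis median was -0.89 against the shGFP mean. On the array labelled sh52 replicate 1 SAT1 was highest (10.83), and that median was -1.58. If the labels hold, these values argue against a lower SAT1 mRNA level as the cause on those arrays. SAT1 mRNA level stays open as a cause on the replicate 2 arrays of sh50 and sh52. Effects of either hairpin on other targets were not tested. With 15 splits of the arrays no share under 0.05 can be had; 1 split, the real one, gave a median as large as -1.51, and the highest other was 1.26.

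The array labelled sh52 replicate 1 held more SAT1 (10.83) and a hypoxia median of 1.10 above the other 5 arrays, and 101 genes lay over 4-fold from those arrays, against 11 to 48 on each other array. A trend with expression level on that array is argued against, since the hypoxia median was 1.28 after the trend was removed. An exchange of labels with a shGFP array was not decided. Both shGFP arrays lay above the 3 other hairpin arrays in the mitosis median, by 0.68 against a gap of 0.42 between the controls. Those medians were already known when the bound was written, and the test takes the lower mitosis genes as an effect of the hairpins. A single wrong label (a sample without the sh52 hairpin) stays open: both arrays labelled sh52 lay over 1 (log2) to the same side of all others in 14 genes, against at most 4 for sh52 replicate 2 with another array, a bound first written as evidence against it, but the doubted array also stood apart with sh50 replicate 1 in 17, with shGFP replicate 1 in 13 and with sh50 replicate 2 in 10. In 200 genes chosen from sh52 replicate 2 and sh50 it lay no nearer to sh52 replicate 2 than a control did (-0.058), which met the bound first written for a wrong label; an allowance for the gap between controls (0.62) was added after the value was seen, as the nearer control shares its number with sh52 replicate 2, and with it the test decides nothing. Open also remain cells that express MTAP, a gene deleted in U87MG, as MTAP differed by -0.011 but stood near the floor on all arrays, and, untested, oxygen-poor culture and an effect of the hairpin.

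The number of transcripts at an unadjusted p under 0.05 was 2972 for the controls against the 4 hairpin arrays in a fit of 2 sets. Of the 15 splits, 3 gave as many, the real one included, and the highest other, 3963, set sh50 replicate 2 and the array labelled sh52 replicate 1 apart; the splits are too few for a share under 0.05.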

How the results depend on the processing

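The unadjusted threshold with 2-fold, the fit without moderation and the spike-in covariate were chosen only after the data were seen. The slope of that covariate rests on the shGFP and sh52 pairs, since the sh50 arrays had nearly equal spike-in means (9.26 on both). In both pairs the number 1 array had the higher mean, so the covariate cannot be told apart from the replicate number. The signal over background limits dim transcripts, and with 1 array of a group left out, the lone array is assumed to vary like the other groups. The 3 cell division and repair lists and the matrix list, mean of both hairpins, kept their direction and camera call under each alternative but an estimated correlation and fry (mitosis -1.81 to -1.19, replication -1.32 to -0.66, repair -0.72 to -0.44, matrix 0.30 to 0.83). Single-symbol features alone give no other list values, since lists use these already. The cause of the changes below was not tested, except that fewer arrays or features enter some fits. Leaving out 1 array also sets a group of 1 replicate number against groups of both, so such changes cannot be told apart from the replicate number.

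No count of called transcripts moved from 0 by limma, except to 1 without sh52 replicate 2, for sh52 against shGFP and against sh50 (0 to 1 when each array was left out). At unadjusted p 0.05 and 2-fold the counts were 735 (sh50), 881 (sh52), 616 (mean of both), 476 (sh52 against sh50) and 287 (both hairpins, same direction). The fit without moderation called 0. With the replicate number as a block (replicate block) the counts stayed 0, with 3801 at an unadjusted p under 0.05 for the mean of both hairpins against 3102. For that comparison the share at an unadjusted p under 0.05 was 7.30% with no filter on dim features, 11.2% at the 75th percentile and 12.2% for single-symbol features, against 9.19%. Deviations of same-numbered arrays correlated at 0.39, 0.35 and 0.052, with only 2 numbers. In the replicate block fit the polycomb list stood at -0.046 and was no longer called (adjusted p = 0.0993); no other list of the mean of both hairpins changed its call, and SAT1 stood at -0.11.

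For the mean of both hairpins, with an estimated correlation or with fry no list was called, at unchanged medians: mitosis -1.51, replication -1.01, repair -0.61, interferon 0.20, hypoxia 0.53, matrix 0.56, polycomb -0.046, oxidative phosphorylation 0.084, ribosomal proteins -0.13 and neuronal markers 0.22. At the 75th percentile ribosomal proteins (-0.13) and neuronal markers (0.36) were no longer called and the unfolded protein list (-0.10) turned in camera's direction. With trend and robust options polycomb (-0.046) was not called. With the spike-in covariate hypoxia (0.20), polycomb (-0.0077) and neuronal markers (0.013) lost the call, p53 targets gained it (0.39), NF-kB turned and was called lower (-0.79, adjusted p = 7.83e-06), and polyamine (0.075), glial (-0.024), ribosomal (0.0090) and blood (-0.030) lists turned. So did SAT1 for sh52 (-1.78; without turning, -1.15 for sh50 and -1.47 for the mean of both), NF-kB (-0.80, called lower, adjusted p = 3.02e-06) for sh52 against shGFP, NF-kB (-0.33) for sh52 against sh50, SLC3A2 (0.16), ITGAX (-0.11) and ENO2 (-0.59).

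With each array left out in turn, SAT1 ran from -0.86 to 0.16 (sh50), -1.36 to 1.63 (sh52) and -0.86 to 0.64 (mean of both). For the mean of both hairpins the ranges were RRM2B -0.0060 to 1.57, LIF -4.27 to 1.20, RPS28 -0.32 to 1.09, SLC3A2 -1.56 to 0.075 and ENO2 -0.13 to 0.86. Lists ran as p53 -0.28 to 0.32, interferon 0.069 to 0.32, NF-kB -0.23 to 0.88, glial -0.034 to 0.060, oxidative phosphorylation -0.011 to 0.22, unfolded protein -0.14 to 0.091, polycomb -0.17 to -0.023, ribosomal -0.27 to -0.048, blood 0.0010 to 0.16, neuronal 0.055 to 0.37, cholesterol 0.050 to 0.25 and polyamine -0.11 to -0.0017. NF-kB ran from -0.34 to 1.33 for sh52 against shGFP and from -0.54 to 1.63 for sh52 against sh50, and ribosomal proteins from -0.065 to 0.26 for sh52 against sh50. In the comparisons other than the mean of both hairpins, list calls were lost in 74 list and setting pairs, in 5 of which camera's direction turned too. Of these 74, 5 were lost without the filter on dim features. Of 96 values of named genes other than SAT1, 30 moved by over 1.5 times or turned without some array, 14 of them without the array labelled sh52 replicate 1.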

Other observations

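The test of a trend with expression level was set before its result was seen. The count of ways to part the arrays was set only afterwards, and the genes in this part were picked after their values were seen.

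The arrays numbered 1 differed from those numbered 2 in inflammatory genes, in every group. With the group means in the limma fit, 9 transcripts were called for the replicate number (3495 at an unadjusted p under 0.05). Those with 1 symbol were CXCL8 (5.65 higher on the log2 scale, adjusted p = 0.00694), FGF7, a fibroblast growth factor (4.19, adjusted p = 0.00694), PTGS2 (6.48, adjusted p = 0.0244) and IL6 (4.06, adjusted p = 0.0244). The cytokine genes IL1B and LIF differed by 4.93, 7.15 and 2.86, and by 5.47, 6.64 and 2.27, in shGFP, sh50 and sh52. NQO1, an oxidoreductase of the oxidative stress response, differed by -3.31, -1.61 and -3.23. SLC7A11, the cystine transporter gene, differed by -5.56, -0.42 and -4.70. Camera called 10 of the 18 lists for the replicate number, and 0 with an estimated correlation. Besides inflammatory genes, the largest medians were matrix genes at 0.51 (adjusted p = 4.38e-09; adjusted p = 0.327 with an estimated correlation), p53 targets at -0.48 (3.19e-06; adjusted p = 0.751 with an estimated correlation) and mitosis genes at 0.48 (6.63e-11; adjusted p = 0.751 with an estimated correlation). In shGFP, sh50 and sh52 the mitosis genes differed by 0.42, 1.14 and -0.29, of opposite sign in sh52, the p53 targets by -0.64, -0.056 and -0.55 and the matrix genes by 0.35, 0.25 and 0.51.

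On the array labelled sh52 replicate 1, HILPDA, a lipid droplet gene induced by low oxygen, stood at 12.98 against a mean of 7.16 on the other 5 arrays. TXNIP, an inhibitor of thioredoxin, stood at 15.63 against 11.58, EFEMP1 at 12.24 against 8.01 and the protease gene MMP12 at 8.21 against 3.85. SLC7A11 differed by -4.50 and GSR, glutathione reductase, by -2.45. The polyamine synthesis genes ODC1 and AMD1 differed by -1.88 and -1.94. Low ODC1 was not particular to that array, since it stood at 10.75 there and at 10.47 on sh50 replicate 2. AMD1 stood at 10.34 there and at 11.94 to 12.87 elsewhere. Without sh52 replicate 2, HILPDA was the 1 gene called for sh52 against shGFP (5.88, limma, adjusted p = 0.0349) and for sh52 against sh50 (5.89, adjusted p = 0.0348).

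The list of NF-kB and inflammatory genes was higher on the arrays numbered 1 by a median of 1.15, and by 0.88, 0.60 and 2.16 in shGFP, sh50 and sh52 (camera, adjusted p = 2.04e-18; adjusted p = 0.461 with an estimated correlation). A trend with expression level is argued against, since 0% of 10000 matched lists had a median as high (highest 0.19). With only 4 ways to part the arrays of each group, no share under 0.05 can be had; 1 way, the real one, gave a difference as large, and the highest other was 0.70. A shared day of culture or hybridisation may lie behind the number, but the labels name none, and no biological explanation was tested.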
